A study of Homo sapiens with 4 samples.

How the data were processed

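The study measured N6-methyladenosine (m6A), a base modification of messenger RNA, by MeRIP-seq. In this assay poly(A) RNA is precipitated with an m6A antibody (IP) and sequenced beside RNA that was not precipitated (input), and peaks mark where the IP exceeds the input. The samples came from 16-HBE, an established human bronchial epithelial cell line. Per the labels, both conditions were exposed to 5% cigarette smoke extract (CSE) for 24 h, and in one of them METTL3, the catalytic subunit of the complex that writes m6A, was knocked down with siRNA. There was no condition without smoke extract. The sample titles name no control siRNA for the CSE condition, so METTL3 reduction cannot be told apart from siRNA transfection itself. The 4 samples were an IP and an input library of each of the 2 conditions. The series' design text gives 3 replicates per condition, but 1 peak list per condition was analysed. Whether the authors pooled or merged the replicates, or used 1 of them, is not given in the sources used here.

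Reads were aligned with HISAT2 2.0.4 to hg19, per the submitters' processing notes. The peak names in the deposited lists start with MACS, the name of a peak caller, whose version and settings are not given in the sources used here. Each deposited list holds 6 columns: chromosome, start, end, name, score and strand. The score is the authors' own value for each deposited peak. Its scale is not stated: the lowest was 50.02 in both lists and values piled up at 3100, as with the p-value score of older MACS versions. The score was used to rank, filter or describe peaks within a list. Where scores from both lists are printed side by side, they are values within each list, and no change in m6A is read from them. Their level was compared across lists only to judge fixed minimum scores. Fixed minimum scores, applied to both lists alike, were tried as an added alternative, but overlapping intervals had higher scores in the knockdown list, and each minimum removed a larger share of the CSE list, so the ratio at such a minimum does not compare the conditions. The last interval of chromosome 1 in the CSE list ended at 249213043, which lies beyond the end of that chromosome in GRCh38, so positions are those of hg19, given here counting from 1.

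Because 7258 intervals had the same start and the same end in both lists, widths are not treated as widths of enrichment measured separately in each condition, and the entries are called intervals below. Names carry a running number. The numbers rose with position along each chromosome without exception in both lists, and most numbers were missing. If the numbers count calls, the lists hold a selection of them. How such a selection was made is not given in the sources used here. The names of both lists hold the term mRNA, but whether it describes the selection is not stated.

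Intervals of both lists were compared by position. An interval counted as overlapping when at least 1 bp was shared with an interval of the other list on the same strand. All others were condition-specific: CSE-only, or knockdown-only for those found only with METTL3 knockdown. To show how much overlap proximity alone gives, the other list was shifted by 1000 or 10000 nt. Shares carry Wilson 95% intervals, ratios of interval numbers carry intervals from the Wilson limits of the knockdown share, and medians carry exact binomial order-statistic intervals. These intervals cover counting error only, treat intervals as independent, and say nothing of differences between cultures. With 1 list per condition no test between conditions was possible and no p-value is given. Read depths of the 4 libraries were not used here, and the lists hold no expression values, so the METTL3 transcript level could not be used to check the knockdown.

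Before the data were examined, the comparisons, the alternatives and the rule for named items were fixed. That rule named genes and also, per condition, the 10 condition-specific intervals with the highest score and, per list, the 5 intervals with the highest score, with ties broken by width and then by position. The lists give no gene names, and the annotation used here belongs to another build, so results on genes, gene lists, transcript positions and sequence motifs were not run. In place of genes, intervals of both lists on one strand with gaps of up to 10 kb were joined into neighbourhoods, and the 10 with the largest net gain and the 10 with the largest net loss of intervals were listed, with ties broken by covered length. This unit, the width classes, the comparison by chromosome and the fixed minimum scores were chosen after seeing the data. Intervals over 300 nt were called wide, and those of up to 300 nt short.

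For 1 comparison in the closing section, the GC content of the longest protein-coding transcript of each gene was taken from GENCODE release 29 and its median computed per chromosome. It is a property of whole chromosomes, and no position was carried between builds. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Overlap was computed with code written for this purpose in place of bedtools, and was tested on simulated data: of 3000 simulated intervals, all 2000 with a partner were recovered and 0 calls differed from a pairwise count under 10 settings. The permutation of labels among neighbouring intervals was tested on simulated labels with and without runs, with 200 permutations each, and told them apart. Alternatives comprised stricter scores, other definitions of overlap, merging of intervals within 100 nt, restriction to chromosomes 1 to 22 and X, removal of the widest and narrowest intervals, and lists of equal length.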

Results

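Transcriptome-wide m6A was compared between smoke-exposed cells of the 16-HBE bronchial epithelial line and the same line exposed after siRNA knockdown of METTL3. The exposure was to cigarette smoke extract (CSE). The question was how the set of m6A-enriched intervals differs in smoke-exposed cells when the main m6A methyltransferase is reduced. Each condition was represented by 1 list of enriched intervals, called from an IP and an input library. There was therefore no replicate spread for any value, and a difference between the lists is a difference between these 2 lists.

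The METTL3 knockdown list was longer than the CSE list, although METTL3 is the catalytic m6A writer. It held 13691 intervals, against 11038 in CSE, a ratio of 1.24 (95% interval 1.21 to 1.27). The covered length differed less, at 8.75 Mb with knockdown and 8.02 Mb in CSE, a ratio of 1.09, because intervals were shorter with knockdown. The median width was 218 nt with knockdown (quartiles 132 and 739) and 285 nt in CSE (quartiles 145 and 930.8). Both strands contributed about equally: 7026 of the knockdown intervals and 5665 of the CSE intervals lay on the plus strand.

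Most intervals of each deposited list overlapped an interval of the other list. Of the CSE intervals, 8838 overlapped a knockdown interval, a share of 80.1% (Wilson 95% interval 79.3 to 80.8). Of the knockdown intervals, 8836 overlapped a CSE interval, a share of 64.5% (63.7 to 65.3). This left 2200 CSE-only and 4855 knockdown-only intervals. Start and end were identical to the base for 7258 intervals, or 82.1% of the overlapping CSE intervals. Intervals lie close together, and with the knockdown list shifted by 1000 nt the share of CSE intervals with an overlap was still 21.5%. With a shift of 10000 nt it was 3.20%. The numbers of overlapping intervals were nearly equal, so the shares differ because the lists differ in length.

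**Figure D1:**
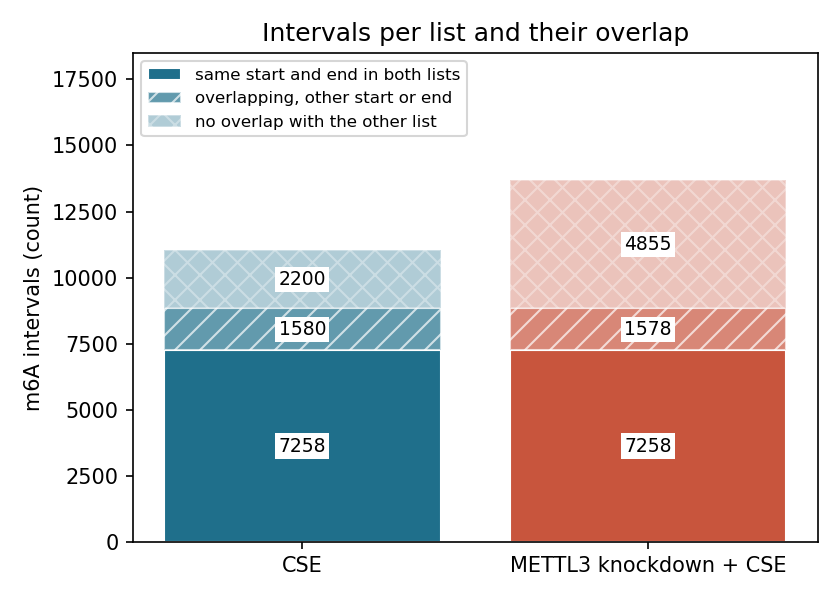
Number of m6A intervals (vertical axis, count) in the CSE and the METTL3 knockdown + CSE list, divided by whether an interval had the same start and end in both lists, overlapped with another start or end, or did not overlap. Both lists share 7258 identical intervals, and the lists differ mainly in the part without overlap, 2200 intervals in CSE and 4855 with knockdown.

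The additional intervals in the knockdown list were short. Among intervals of up to 300 nt, 8022 were listed with knockdown and 5639 in CSE, a ratio of 1.42 (1.37 to 1.47). Among wider intervals the numbers were closer, 5669 and 5399, with a 95% interval of the ratio from 1.012 to 1.090. The ratio was highest for intervals of up to 100 nt, at 1.52 (1.41 to 1.63), and was 1.01 (0.941 to 1.09) for intervals over 1000 and up to 2000 nt. Condition-specific intervals differed accordingly. The median width of knockdown-only intervals was 175 nt (171 to 179), that of CSE-only intervals 361.5 nt (337 to 397), and that of overlapping intervals 267 nt in both lists. Intervals over 300 nt made up 30.3% (29.04 to 31.63) of the knockdown-only set and 54.7% (52.6 to 56.8) of the CSE-only set, beside 47.5% of the overlapping intervals of either list. Widths are those of the deposited intervals, whose borders were identical in both lists for most overlapping intervals. Where only identical borders counted as overlap, overlapping intervals with other borders became condition-specific. Knockdown-only intervals so defined had a median of 250 nt, wider than the 204 nt of shared ones. The CSE-only median was then 731 nt.

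**Figure D2:**
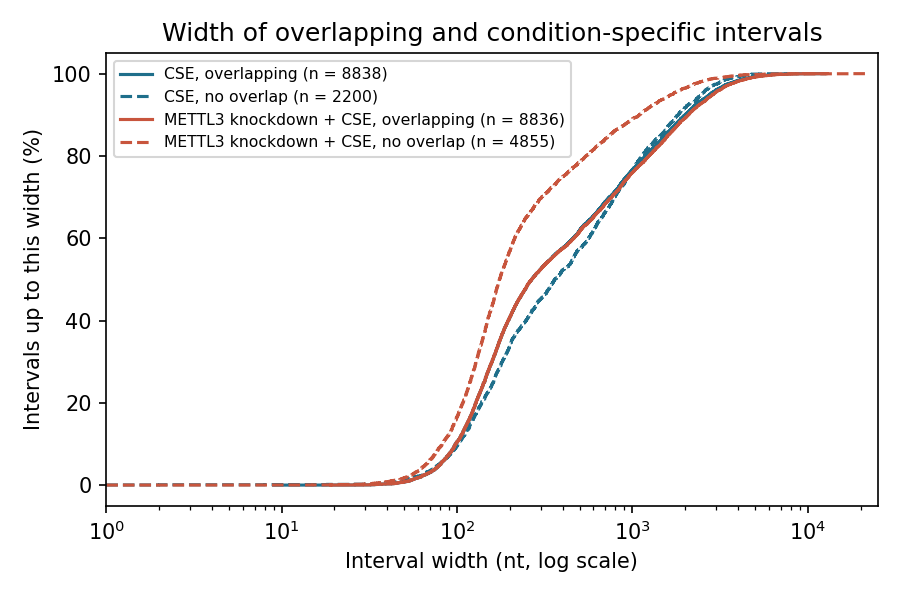
Cumulative share of intervals (vertical axis, %) up to a given width (horizontal axis, nt, log scale) for overlapping intervals (solid lines) and intervals without overlap (dashed lines) of each list. The knockdown-only curve lies to the left, with a median of 175 nt, and the CSE-only curve to the right, with a median of 361.5 nt. The curves of overlapping intervals coincide, both with a median of 267 nt.

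Condition-specific intervals lay at the lower end of the authors' score in both lists. In the CSE list the median score was 108.7 (103.2 to 112.7) for CSE-only intervals and 275.3 (264.4 to 285.7) for overlapping ones. In the knockdown list the medians were 116.5 (113.2 to 120.5) and 506.7 (490.9 to 528.6). When each list was divided by score into 10 classes of equal size, in the lowest class 59.1% of the CSE intervals and 23.9% of the knockdown intervals overlapped the other list. In the highest class the shares were 94.4% and 92.3%. Overlap also followed width in the knockdown list, from 53.6% (51.3 to 55.9) of intervals up to 100 nt to 84.8% (82.6 to 86.7) of those over 2000 nt. In the CSE list it stayed between 75.5% and 83.3% across the 6 width classes. Some condition-specific intervals nevertheless had scores of 3100 or more, 36 of them in CSE and 88 with knockdown.

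**Figure D3:**
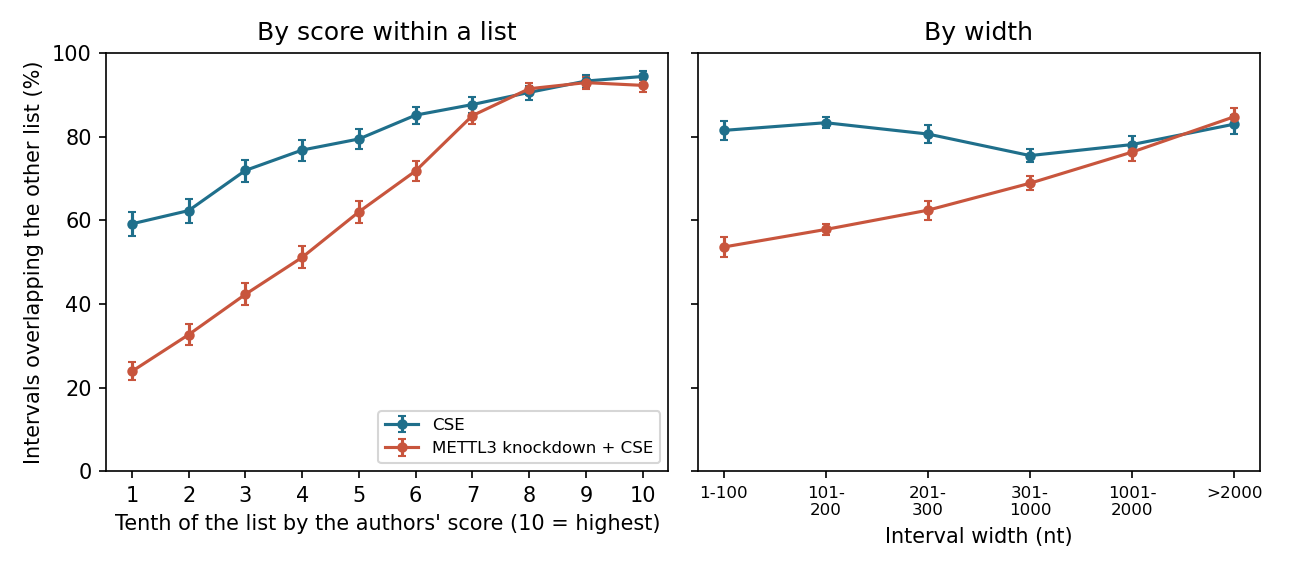
Share of intervals that overlap the other list (vertical axis, %, points with Wilson 95% intervals) by class of the authors' score within each list (left, 10 classes of equal size) and by interval width in nt (right). The share rises with score up to 94.4% in the highest class in CSE, levels off with knockdown at 92.9% and 92.3% in the highest 2 classes, and rises with width in the knockdown list, from 53.6% to 84.8%.

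The excess of intervals with knockdown was seen on each of the 23 chromosomes 1 to 22 and X, but differed in size. It was smallest on chromosome 22, with 252 intervals against 238 in CSE, a ratio of 1.06 (0.887 to 1.26). Chromosome 16 followed with a ratio of 1.10 (0.968 to 1.25) and chromosome 19 with 1.13 (1.01 to 1.25). The ratio was highest on chromosome 13, at 1.35 (1.142 to 1.601), with 315 intervals against 233, and was 1.34 (1.19 to 1.51) on chromosome 4. The 95% intervals of these ratios overlap one another. On all 23 chromosomes the median width of knockdown-only intervals was below that of CSE-only intervals.

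**Figure D4:**
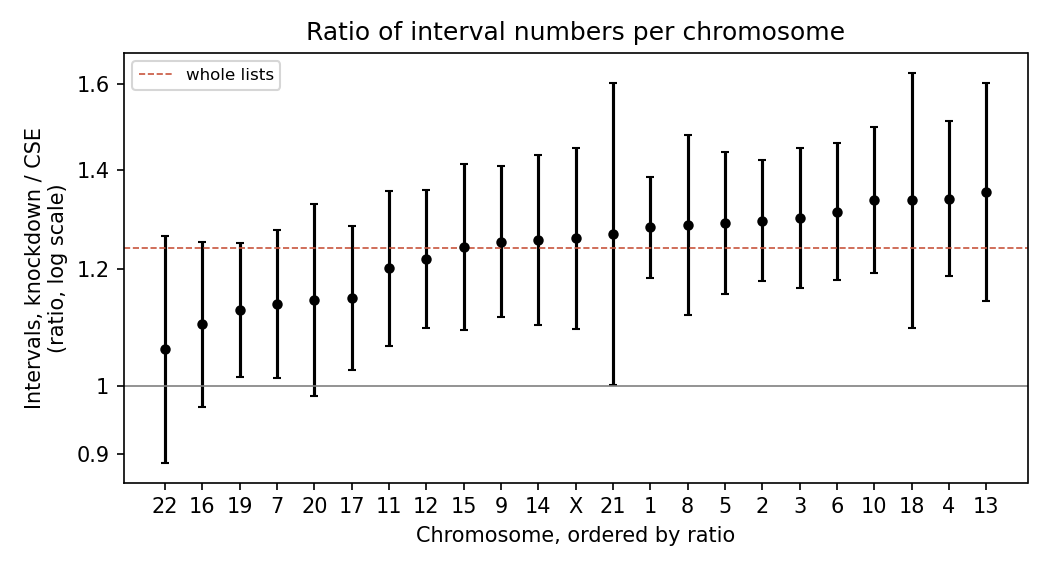
Ratio of the number of intervals with METTL3 knockdown to that in CSE (vertical axis, log scale) for chromosomes 1 to 22 and X, ordered by ratio. Points are ratios, bars are 95% intervals for counting error, and the dashed line is the ratio of the whole lists, 1.24. Ratios run from 1.06 on chromosome 22 to 1.35 on chromosome 13.

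Joining intervals of both lists on one strand with gaps up to 10 kb gave 9917 neighbourhoods. Of these, 6078 held an interval common to both lists, 2420 held knockdown-only intervals alone and 1256 held CSE-only intervals alone. More neighbourhoods gained intervals with knockdown than lost them, 3636 against 1685. This is not a separate result, since the whole lists held 4855 knockdown-only and 2200 CSE-only intervals. The largest net gain was 11 intervals, in a 45.3 kb stretch of the plus strand of chromosome 1 (hg19, 214787057 to 214832371). Here 2 wide intervals of 3404 and 2844 nt and a short one of 153 nt were listed in both conditions with identical borders. Their scores, in that order, were 529.8, 618.4 and 65.1 in the CSE list, and 3100, 3100 and 1114.8 in the knockdown list. With knockdown 11 further intervals of 122 to 292 nt appeared on both sides of them, with scores from 54.5 to 577.5. The neighbourhood with the next largest gain, 9 intervals, lay on the minus strand of chromosome 12 (93192668 to 93226626), where 1 interval was common to both lists. Gains of 7 intervals each were found on the plus strand of chromosome 1 (39875176 to 39906797), the plus strand of chromosome 19 (50770134 to 50805126) and the minus strand of chromosome 12 (120189855 to 120214646). None of these 5 neighbourhoods held a CSE-only interval.

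One neighbourhood stood apart among the losses. On the plus strand of chromosome 5 (hg19, 140710252 to 140802824), 12 of the 16 CSE intervals had no overlap with the knockdown list. They were wide, from 1515 to 2823 nt with a median of 2464.5 nt, in contrast to the short intervals that were gained elsewhere. Their scores ran from 55.5 to 516.5. The other 4 CSE intervals of this stretch overlapped 5 knockdown intervals. Their scores ran from 262.4 to 918.3 in the CSE list, and those of the 5 from 131.6 to 416.6 in the knockdown list. Among them, the interval starting at 140767452 scored 333.1 in the CSE list and 412.4 in the knockdown list. The next largest losses were 4 intervals each, on the plus strand of chromosome 20 (34800194 to 34832848), the minus strand of chromosome 19 (9011322 to 9026315) and the plus strand of chromosome X (2638397 to 2644414). With gaps of up to 50 kb the chromosome 5 neighbourhood was unchanged and still the largest loss, while the largest gain became 12 intervals, on the minus strand of chromosome 9 (123156790 to 123313180) and again on the minus strand of chromosome 12 (120127956 to 120214646). The genes at these positions were not analysed here.

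**Figure D5:**
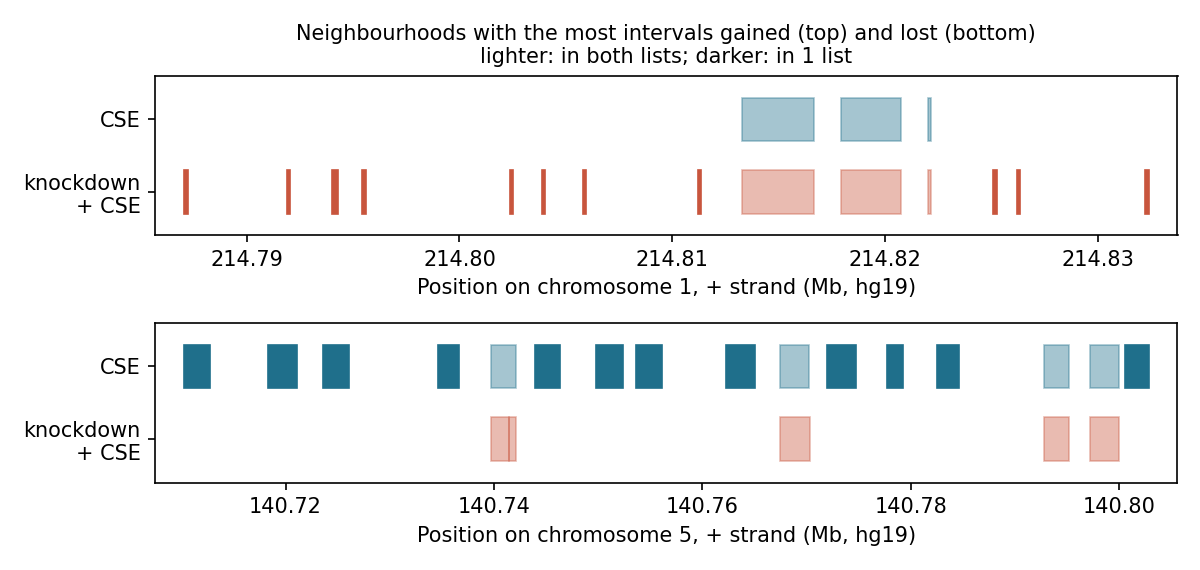
Positions (horizontal axis, Mb, hg19) of listed intervals in the neighbourhoods with the largest gain, on chromosome 1 (top), and the largest loss, on chromosome 5 (bottom), with a row for CSE and a row for METTL3 knockdown + CSE. Lighter boxes overlap the other list and darker ones do not. Short intervals, 11 in number, were added with knockdown on chromosome 1, and 12 wide intervals were listed in CSE alone on chromosome 5.

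Among CSE-only intervals the highest score, 3209.5, belonged to a 1115 nt interval on the plus strand of chromosome 11 (82876642 to 82877756). It was followed by 167 nt on the plus strand of chromosome 10 (6146894 to 6147060), with a score of 3192.7, and by 187 nt on the plus strand of chromosome 20 (43629808 to 43629994), with a score of 3133.6. Each of these had a knockdown interval on the same strand within 3543 nt, at 1713, 3543 and 175 nt. The other 7 of the first 10 had scores of 3100 and widths from 982 to 2345 nt. The widest, on the plus strand of chromosome 3 (5024521 to 5026865), had no listed knockdown interval on its strand within 299038 nt. A 2046 nt interval on the minus strand of chromosome 2 (151324707 to 151326752) had none listed within 819354 nt. Between the flanking listed knockdown intervals of either strand, 14 and 12 numbers were unlisted, so unlisted knockdown calls there are not excluded.

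Among knockdown-only intervals the highest score, 3227.0, belonged to an 89 nt interval on the minus strand of chromosome 14 (23550957 to 23551045), which was also among the first 5 of the whole knockdown list. A 924 nt interval on the plus strand of chromosome 6 (32948359 to 32949282) scored 3169.9, with the nearest listed CSE interval of its strand 120730 nt away. Between the flanking listed CSE intervals of either strand, 6 numbers were unlisted. Short intervals on the plus strand of chromosome 1 followed, 195 nt at 27269362 to 27269556 with a score of 3160.8 and 138 nt at 183101535 to 183101672 with a score of 3128.3. A pair of wide intervals lay close together on the plus strand of chromosome 6, 2429 nt at 31783291 to 31785719 and 2520 nt at 31795512 to 31798031, both with a score of 3100. The rest of the first 10 scored 3100, with widths from 2108 to 2342 nt. The widest of these, on the plus strand of chromosome 1 (181057638 to 181059979), had its nearest listed CSE interval on that strand 992572 nt away. For the 2108 nt interval on the plus strand of chromosome 20 (48807120 to 48809227) the distance was 317630 nt. Between the flanking CSE intervals, 21 and 23 numbers were unlisted. The others had a CSE interval within 35076 nt. The highest-scoring intervals of each whole list were almost all common to both. All of the first 5 in CSE overlapped the knockdown list, headed by a 3031 nt interval on the minus strand of chromosome X (39931403 to 39934433) with a score of 3233.1. In the knockdown list 4 of the first 5 overlapped the CSE list, headed by 641 nt on the plus strand of chromosome 7 (77378741 to 77379381) with the same score of 3233.1.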

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

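Of the tests in this part, those on the selection of calls, on minimum scores and on GC content were chosen after the results they bear on had been seen. The others were fixed before their outcome was known. Read depths were not used here, so a deeper IP or input library in one condition stays open as an explanation for each pattern below.

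The deposited lists hold a minority of the running numbers. The highest number in the names was 49879 in CSE and 48847 with knockdown, so 38841 numbers in CSE and 35156 with knockdown had no listed interval. Listed intervals made up 22.1% of the numbers in CSE and 28.0% with knockdown. This stood out because, if the numbers count calls, it is a set of calls outside every comparison above.

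The longer list after knockdown of an m6A writer is the first pattern. Weak calls near the score threshold stay open as an explanation, and 81.2% of knockdown-only (80.1 to 82.3) and 75.5% of CSE-only intervals (73.6 to 77.2) lay in the lower 5 of 10 score classes of their list. Limiting both lists to scores of at least 100 gave a ratio of 1.30, but this decides nothing, since overlapping intervals had median scores of 275.3 in CSE and 506.7 with knockdown, so that a fixed minimum is not equally strict in both lists. The selection of calls by the authors stays open too: the highest numbers had a ratio of 0.979, so if the numbers count calls there were about as many in both conditions, and the excess appeared in how many of them were listed. Reduced METTL3 activity, the difference named by the design, could act on that selection too and was not tested separately. With no control siRNA named, an effect of transfection cannot be told apart from it.

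The second pattern is the difference in width, a median of 175 nt for knockdown-only against 361.5 nt for CSE-only intervals. Overlapping knockdown intervals drawn to the scores of knockdown-only ones had a median width of 240 nt. It was no lower than 218 nt in any of 100 draws, so at equal scores knockdown-only intervals were the shorter ones. In CSE the order was the opposite, with 210 nt for overlapping intervals drawn to the scores of CSE-only ones. Overlapping intervals also had to be listed in the other condition, so they are not a neutral sample of weak calls. Weak calls near the score threshold therefore stay open as an explanation. A few chromosomes do not carry the difference in width, since the knockdown-only median was the lower one on 23 of 23 chromosomes. A candidate explanation was a shift of enrichment from long towards short exons when METTL3 is reduced. Intervals over 300 nt were not fewer with knockdown, however, at 5669 against 5399 in CSE. For these 2 lists, the counts argue against a shift that takes wide intervals away on balance. Whether the intervals are exons was not tested against annotation of this build, and differences in RNA fragment size or IP background stay open.

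The third pattern is the unequal gain by chromosome. Across the 23 chromosomes, which are not replicates, the log2 ratio of interval numbers fell with the median GC content of transcripts, from 42.6% to 58.6%, with Spearman's rho of -0.88 and Pearson's r of -0.89. Without chromosomes 19 and 22, the farthest in GC content, r was -0.85. Permuting GC content over chromosomes 1000 times gave values of rho between -0.61 and 0.69. The division into short and wide intervals does not account for the relation, since rho was -0.75 among intervals up to 300 nt and -0.72 among wider ones. The lowest permuted rho in these classes was -0.58 and -0.67, and width still varied within each class. A GC-dependent difference between the libraries is consistent with these values, but GC content varies together with gene density and gene structure along chromosomes, so a biological difference between GC-poor and GC-rich genes stays open.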

How the results depend on the processing

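Of 70 values under alternatives, 41 stayed within the counting error or within 1.5 times the reported count, and 29 moved. Reversal was assessed only for ratios of interval numbers, and 0 of those reversed. Minimum scores, identical borders and widths of specific intervals under other settings were added after seeing the data. In the upper 50% of each list by score there were 5519 CSE and 6846 knockdown intervals, by construction, with median widths of 432 and 288.5 nt and overlapping shares of 90.2% and 86.7%. At scores of at least 100, 200 and 500 the ratio of list lengths was 1.30, 1.38 and 1.48, with 5879 and 8098 intervals at 200 and 3296 and 4870 at 500. At 100 the median widths were 305 and 485.5 nt for overlapping and CSE-only intervals, and 306 and 187 nt for overlapping and knockdown-only ones. Reciprocal overlap of 50% gave 79.2% in CSE. Drawing the longer list down 100 times gave a median of 64.6% in CSE, by construction. Counting only identical borders gave shares of 65.8% and 53.01%, 3780 CSE-only intervals, median widths of 204 nt for shared intervals of both lists, 731 nt for CSE-only and 250 nt for knockdown-only ones, and median scores of 153.3, 144.5 and 534.5 for CSE-only, knockdown-only and shared knockdown intervals. With this definition knockdown-only intervals were wider than shared ones, whereas the main comparison gave 175 nt against 267 nt. The stricter definition counts overlapping intervals with other borders as condition-specific, which raised the knockdown-only number from 4855 to 6433. The intervals moved in this way were wider than the rest, since the median of shared intervals fell from 267 to 204 nt. The change of order thus came with the definition. Merging within 100 nt, ignoring strand and leaving out chromosomes or extreme widths moved no value beyond the limits given first. Merging and the choice of chromosomes changed little to begin with. They left 11032 and 11022 of 11038 CSE intervals, and 13679 and 13678 of 13691 knockdown intervals. The alternatives for genes, gene lists, transcript positions and motifs were not run. No paired analysis was possible because there was 1 list per condition. Without replicates or read depths, differences between these lists cannot be set against the spread between cultures.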

Other observations

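Gained intervals tended to be neighbours. Among knockdown-only intervals, 23.6% had a knockdown-only interval as their nearest one on the same strand within 10 kb. In 1000 permutations of the labels within 10 classes of the list by score, the share had a median of 19.2% and reached at most 21.4%. For CSE-only intervals the share was 10.4%, inside the range of its permutations, 6.59% to 12.9%. It lay above their median of 9.18%, and 65 of the 1000 permutations were at least as high. A hypothesis fixed before this test was run is that neighbouring intervals, which may belong to the same transcripts, are gained together with knockdown, and the value of 23.6% is consistent with it. A higher abundance of those transcripts, which would bring several calls over the threshold at once, was not tested, and the permutations match on score but not on how densely intervals lie.

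Few condition-specific intervals faced a condition-specific interval of the other list nearby. Within 5 kb on the same strand, 252 of the CSE-only intervals (11.5%, Wilson 95% interval 10.2 to 12.9) had a knockdown-only one, and within 1 kb 94 had one (4.27%, 3.50 to 5.20). Of the knockdown-only intervals, 263 had a CSE-only one within 5 kb (5.42%, 4.81 to 6.09). Most gains and losses were therefore not exchanges of one interval for its neighbour within those distances.

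If the running numbers count calls, they show where a condition-specific interval had no separate unlisted call in the other condition. Between the flanking listed intervals of the CSE list, 182 of 4836 knockdown-only intervals (3.76%, 3.26 to 4.34) had no unlisted number, and so no unlisted CSE call in that place. For CSE-only intervals in the knockdown list it was 180 of 2187 (8.23%, 7.15 to 9.46). Such places were the exception: of all pairs of neighbouring listed intervals, 37.1% in the CSE list and 43.1% in the knockdown list had consecutive numbers. Condition-specific intervals thus mostly lay where the other condition had unlisted numbers. The distance between flanking intervals was not matched in this comparison. Counting also places with fewer unlisted numbers than condition-specific intervals, at least 267 knockdown-only (5.52%) and at least 216 CSE-only intervals (9.88%) had no separate call in the other condition, if each call gives at most 1 interval. These are minimums only if listed intervals keep the extent of their calls and no flanking call was shortened before deposit, which was not tested. For the rest, 1 or more numbers of the other condition were unlisted between the flanking intervals, and positions of any such calls are not known here. Of the first 10 intervals by score in each condition-specific set, those without an unlisted call were the 1115 nt interval on chromosome 11 in CSE and, with knockdown, the 195 nt and 138 nt intervals on chromosome 1 that began at 27269362 and 183101535.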
